A study of Arabidopsis thaliana with 4 samples.

How the data were processed

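DNase I-seq libraries of Bur-0, Bay-0, Est-1 and Tsu-1 seedlings were analysed, 1 library per accession. Per the labels' protocols, seeds were stratified for 2 to 4 days on agar (0.8%) and grown for 7 days in long days, with 16 h of light at 22°C and 8 h of dark at 20°C. Nuclei were captured through biotin and then digested at 25°C for 3 minutes with DNase I (45 units), and small double-cut fragments were sequenced from Illumina TruSeq v2 libraries. Samples were grouped by the accession in their source label. The labels of all 4 samples give Col-0 as genetic background although their titles name other accessions, and the series text writes Tsu-0 where the sample labels write Tsu-1; the sample labels were followed.

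Bowtie 0.12.7 and the TAIR10 genome build are named per the submitters' processing notes. The peak caller, its threshold, read filters and the sequencing depth are not given in the sources used here. Each deposited list belongs to 1 library, and its columns follow the narrowPeak layout with no header. The deposited signal is a whole number per peak, set by the authors, with no scaling stated. The deposited −log10 p column holds the authors' value for each peak, with a ceiling of 324 that 6.03 to 13.0% of peaks reach and lowest values of 3.32 to 3.40. Signal was used to rank or filter peaks within a list, with −log10 p to break ties when lists were shortened, and the highest signal of each list is also given as a multiple of its list median. Median signal was 130 in Bur-0, 155 in Bay-0, 172 in Est-1 and 108 in Tsu-1; these medians are not compared between lists. The Est-1 list has exactly 30000 peaks with organelles included, against 25567, 29117 and 27634 for Bur-0, Bay-0 and Tsu-1, and whether list length was limited is not given in the sources used here. Reads aligned to a Col-0 reference can be lost where an accession differs from it, so an absent peak can reflect sequence as well as chromatin.

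From these lists, peaks on the 5 nuclear chromosomes were compared, and organelle peaks were counted apart. Pairwise sharing is the share of the peaks of both lists that overlap a peak of the other list by at least 1 bp, and the Jaccard index is shared bases over covered bases. Regions are unions of touching or overlapping peaks. A region is missing from an accession when the other 3 lists hold it, and private when no other list does. Rank is the percentile of signal within a list. Backgrounds were 100 random placements of each list within its chromosomes, 100 placements at the same offset from random gene ends, 100000 random positions, and 100 random reassignments of the missing regions for runs of neighbours. Shares have 95% exact (Clopper-Pearson) intervals, which cover counting error only; with 1 library per accession no p-value was computed.

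Gene names and positions came from a RefSeq gene table of assembly TAIR10.1. Its fit to the peaks was checked by sliding regions over gene ends by up to 20 kb: in all 15 stretches, chromosomes and their parts, the best shift was at most 50 bp. The table carries no strand, exons, descriptions or sequence. The planned windows around transcription starts were therefore replaced by windows at both gene ends, exons and introns were not told apart, gene families were found by keyword in symbols and synonyms (15 families with at least 10 genes), and the planned count of short sequence motifs was not run. A peak midpoint was assigned to a gene end (within 400 bp), then a gene interior, then a flank (within 1000 bp), and otherwise was distal; 27444 protein-coding genes were used. Gene-poor stretches are 100 kb bins with fewer than 15 protein-coding genes. Of the 261 genes on 17 fixed lists, 260 were found; AOP2 was not among the protein-coding genes and was not used. Each list was set against 10000 random lists of the same size, matched on quintile of the space to the neighbouring genes.

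The gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names all list genes with a peak in exactly 3 or exactly 1 accessions (as they were at most 25), per accession the 4 missing and the 4 private regions with the highest rank (the lowest of the ranks in the lists that hold the region), the 5 regions in all 4 lists with the highest lowest rank, and UBQ10 and ACT2. Regions are named by the nearest protein-coding gene. Other genes named as examples of a list or run were chosen after their values were seen. Alternatives were another overlap, a merging distance of 150 bp, lists of equal length (25298 peaks), the stronger part of each list, other windows and gene sets. Alternatives added later were the wider gene window, random lists matched again under each window and with equally long lists, placement at gene ends, comparisons without one accession, and missing regions with no own peak within 300 bp.

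Region counts, overlaps, nearby own peaks, gene-end shares, gene windows, runs and random lists were tested on simulated data; gene classes, ribosomal RNA loci and rank differences were not. All counts of 25092 simulated regions matched the truth, and 5% of 200 random lists fell outside the middle 95% of random lists. All of 50 lists of 20 genes with 18 called lay above it. The simulated regions were chosen to stand well apart and their peaks were shifted little. Peaks of a real list stood as little as 10 bp apart, so merging of such close peaks was not tested. Spacing quintiles were assigned at random in the list check, so the matching was not tested either. Planted runs gave 46.3% of missing regions in runs, against 26.8% after random reassignment. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.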

Results

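Chromatin accessibility was profiled in whole 7-day-old seedlings of 4 natural accessions of Arabidopsis thaliana, Bur-0, Bay-0, Est-1 and Tsu-1, by DNase I-seq, in which small fragments released by a pair of nearby DNase I cuts are sequenced and pile up where DNA is open. The nuclei came from lines carrying the INTACT transgenes, which place a biotin tag on nuclei, here with UBQ10 and ACT2 named in the line label, so that nuclei of most cell types can be captured together. Each accession had 1 library and 1 list of peaks, so no difference between accessions has a replicate check, and no p-value is given. Peaks stood on the TAIR10 reference, and nearly all were exactly 150 bp wide (99.9% in each list). The 5 nuclear chromosomes held 25298 peaks in Bur-0, 28821 in Bay-0, 29699 in Est-1 and 27388 in Tsu-1, covering 3799, 4326, 4457 and 4111 kb. Sequencing depth is unknown here. Intervals are 95% exact (Clopper-Pearson) intervals and cover counting error only.

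Regions called in all 4 accessions were the largest group. Merging touching or overlapping peaks gave 36153 regions, and 19642 of them, 54.3% (53.8 to 54.8), held a peak in all 4 accessions. A further 5610 regions were called in 3 accessions, 4568 in 2 and 6333 in 1. The share in all 4 depended on the rule, at 60.4% with peaks merged up to 150 bp apart, 56.0% with equally long lists, 49.6% with only the stronger 50% of each list and 40.4% where an overlap had to cover at least 50% of both peaks. When the peaks were placed at random on the same chromosome, 24.5 regions on average reached all 4 lists, and 391 did when they were placed at the same offset from random gene ends. Among the pairs, Bay-0 and Est-1 shared the largest part of their peaks, 86.0% (85.7 to 86.3), followed by Bay-0 and Tsu-1 with 85.3% and Est-1 and Tsu-1 with 84.5%. The pairs with Bur-0 lay lower, at 81.4% with Tsu-1, 81.1% with Bay-0 and 79.7% (79.3 to 80.0) with Est-1. In shared bases the Jaccard index ran from 0.477 for Bur-0 and Est-1 to 0.584 for Bay-0 and Est-1. Random placement gave 6.38 to 7.10% shared peaks on average, and placement at random gene ends 13.9 to 15.7%.

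**Figure D1:**
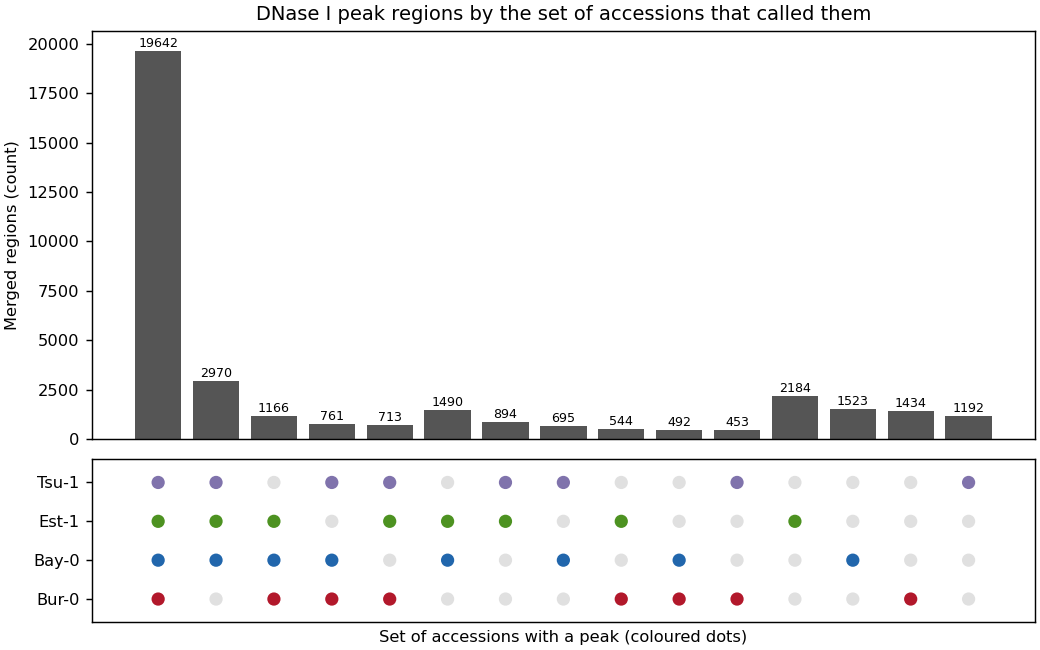
Number of merged DNase I peak regions (vertical axis, count) for each set of accessions that called them; coloured dots under a bar mark the accessions with a peak. Regions in all 4 accessions number 19642, and the next largest set, with 2970 regions, is the one lacking a peak in Bur-0 alone.

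The 5 strongest regions shared by the 4 accessions stood in or nearest to RAV1, TIC and genes with no symbol. The authors' signal value per peak is used here to rank peaks within a list, as a percentile with 100 at the top. Of the 5 regions with the highest lowest rank, 1 lay inside AT2G12905 (chromosome 2, 5296381 to 5296550), and its rank was at least 99.9 in every list. Others stood nearest to RAV1, a transcription factor with AP2 and B3 domains (chromosome 1, 4540681 to 4540870), and TIC, the clock regulator TIME FOR COFFEE (chromosome 3, 7912521 to 7912670), with AT1G13360 (chromosome 1, 4580041 to 4580190) and AT1G69760 (chromosome 1, 26243561 to 26243750) making up the set. Both genes named in the line label had peaks in all 4 accessions. If the transgenes carry copies of these promoters, reads from them would align to the same places. The ranks may then not measure the native genes alone. A region 452 bp from UBQ10, a polyubiquitin gene with a widely active promoter (chromosome 4, 2717441 to 2717610), ranked from 99.5 in Bur-0 to 100 in Bay-0. A region next to ACT2, a vegetative actin (chromosome 3, 6474621 to 6474790), ranked from 96.2 in Tsu-1 to 98.3 in Bur-0.

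Bur-0 lacked more of the common regions than any other accession. Of the 22612 regions called in Bay-0, Est-1 and Tsu-1, 2970 had no Bur-0 peak, 13.1% (12.7 to 13.6). The same share was 3.5% (3.25 to 3.76) for Bay-0, 3.73% (3.47 to 4.00) for Est-1 and 5.60% (5.29 to 5.92) for Tsu-1. Regions private to 1 accession were most numerous in Est-1, the longest list, with 2184, against 1523 in Bay-0, 1434 in Bur-0 and 1192 in Tsu-1. The regions that Bur-0 lacked were weak elsewhere, with a median rank of 25.6 in the other 3 lists, against 62.4 for the regions it shared with them; the regions that Tsu-1, Bay-0 and Est-1 lacked had medians of 25.0, 35.0 and 35.7. Among regions that ranked above 50 in each of the other 3 lists, the share without a peak fell to 3.44% (3.10 to 3.79) in Bur-0, 1.27% (1.05 to 1.51) in Bay-0, 1.38% (1.16 to 1.63) in Est-1 and 1.28% (1.07 to 1.52) in Tsu-1. With every list held to its 25298 strongest peaks, Bur-0 lacked 1850 regions and the next highest count was 998. Private regions then numbered 2235 in Bur-0 and 1254 in Est-1. The Bur-0 list stayed whole at this length, so its private count could only rise. A missing call is not a measure of closed chromatin.

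**Figure D2:**
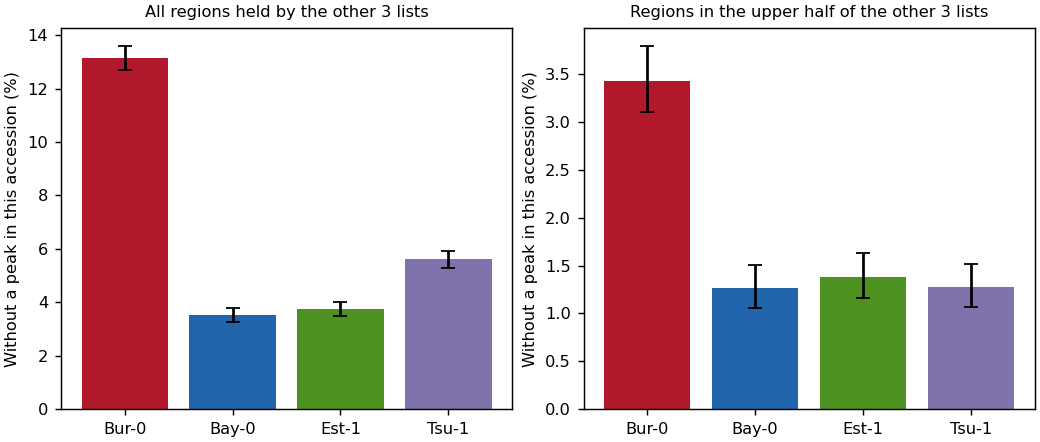
Percent of regions without a peak in each accession (vertical axes, percent of the regions that the other 3 lists held), for all such regions (left) and for those that ranked above 50 in each of the other 3 lists (right). Bars are shares of 1 library per accession and whiskers 95% exact intervals; Bur-0 stands at 13.1% and 3.44%, above the other accessions in both panels.

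Strong regions with no call in 1 accession often stood beside a peak of that same accession. Of 763 missing regions that ranked above 50 in each of the other 3 lists, 363 (47.6%, 44.0 to 51.2) had such a peak within 150 bp. By rank, the leading regions that Bur-0 lacked were nearest to AT5G45350 (chromosome 5, 18378701 to 18378850), MPK9, a mitogen-activated protein kinase (chromosome 3, 6173801 to 6173950), SLK2, a SEUSS-like transcriptional co-regulator (chromosome 5, 24939521 to 24939670) and RALFL21, a RALF-like peptide gene (chromosome 3, 1292041 to 1292230). The lowest of their ranks in the other 3 lists was 99.0, and each had a Bur-0 peak 50 to 110 bp away. Est-1 lacked regions nearest to AT2G41890, AT5G25280, AT1G75530 and AT1G03220 (2314, 721, 1480 and 957 bp away), with its own peaks 30 to 110 bp from the regions. Of the 16 missing regions named, 4 per accession, 13 had an own peak within 300 bp, at 30 to 170 bp. Of the 16 private regions named, 13 had a peak of another list within 300 bp. Over all private regions this share was lower, at 54.7% in Bur-0, 34.7% in Bay-0, 31.9% in Est-1 and 45.9% in Tsu-1.

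The remaining 3 missing regions had no own peak within 300 bp. Bay-0 had no peak at a region nearest AT5G35110 (chromosome 5, 13369841 to 13370010) that was the strongest of all in Est-1 (signal 2400) and ranked 99.9 in Bur-0, and its closest peak lay 8270 bp away. It also lacked a region near MKK9, a mitogen-activated protein kinase kinase (chromosome 1, 27638321 to 27638650), with its closest peak 1890 bp away. Tsu-1 had no call inside AT3G27240 (chromosome 3, 10057421 to 10057590), where the lowest rank of the other lists was 99.4 and its own closest peak was 1110 bp away. The other named regions without a Bay-0 call were nearest to EDA12 (5271 bp away) and AT5G08139 (59 bp away), with own peaks at 30 and 90 bp. Those without a Tsu-1 call were nearest to AOX1A, the mitochondrial alternative oxidase, TIC, and BBD1, a nuclease linked to basal defence. They lay 1109, 1540 and 967 bp from these genes, with own peaks at 170, 30 and 70 bp.

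Leading private regions were nearest to genes of several kinds. In Bur-0 they were AT3G20362 (signal 2072), AT2G01008 (1372), GH3.1, a member of the auxin-conjugating GH3 family (1103), and AT5G30520 (806), the last in sequence where the nearest protein-coding gene was 91097 bp away. The AT2G01008 region lay at the start of chromosome 2 (2541 to 2690). Its rank of 99.8735 equals the median rank of the 9 Bur-0 peaks around the 45S ribosomal RNA genes on that chromosome. Reads of repeated sequence could have raised it, which was not tested. Private Bay-0 regions stood nearest to RLT2, a RINGLET-type homeobox protein, AT4G19530, AT1G51810 and AT3G57810, at distances of 2761, 2089, 519 and 1825 bp. In Est-1 they stood nearest to AT2G46360, UBQ10, AP2, a floral homeotic regulator, and PYL4, an abscisic acid receptor. These genes were 344, 222, 2635 and 299 bp away, and each region had a peak of another list 30 to 70 bp away. Private Tsu-1 regions stood nearest to AT3G26539, RLT2, AT5G40460 and STN7, the kinase that phosphorylates light-harvesting proteins. Those genes were 4093, 2941, 1247 and 2153 bp away. The RLT2 regions of Bay-0 (chromosome 5, 17792921 to 17793070) and Tsu-1 (17793101 to 17793250) were adjacent calls 30 bp apart, each counted as private. No peak of another list stood nearer to either.

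Open chromatin concentrated at the ends of genes in every accession. The gene table used carries no strand, so starts and ends of genes were not told apart. Peak midpoints within 400 bp of either end of a protein-coding gene made up 55.5% (54.8 to 56.1) of the Bur-0 peaks, 57.0% (56.5 to 57.6) in Bay-0, 56.6% (56.0 to 57.1) in Est-1 and 55.4% (54.8 to 56.0) in Tsu-1, against 29.5% of random positions. Interiors of genes were depleted, with 6.27 to 6.48% of peaks against 35.6% of random positions, and gene-poor 100 kb stretches held 2.86 to 3.08% of peaks against 17.6%. Regions called in all 4 accessions were at gene ends more often than those called in 1, 57.1% (56.4 to 57.8) against 49.3% (48.1 to 50.6). Regions called in 1 accession were in gene-poor stretches more often, 6.22% (5.64 to 6.84) against 2.41% (2.2 to 2.63). Among private regions, those of Bur-0 and Tsu-1 were at gene ends in 42.8% (40.2 to 45.4) and 45.4% (42.5 to 48.3) of cases, and those of Bay-0 and Est-1 in 54.2% (51.7 to 56.8) and 52.3% (50.2 to 54.4).

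Genes of photosynthesis, the clock, light and auxin were open in all 4 accessions more often than other genes with similar spacing. A gene was counted as open where a peak overlapped the window from 1000 bp outside to 200 bp inside either gene end. The same peak can fall in the windows of neighbouring genes. Peaks of the 4 lists could stand at different places in a window. HSP101, MOT1 and TIP41 were counted as open in all 4 accessions although none of their regions was called in all 4. Of the 27444 protein-coding genes, 14733 (53.7%) had such a peak in all 4 accessions, 5359 (19.5%) in some and 7352 in none. All 25 nuclear photosynthesis genes were open in every accession, among them RBCS1A, a small subunit of Rubisco, and LHCA2, a light-harvesting protein of photosystem I. So were 15 of 16 clock genes (93.8%, 69.8 to 99.8), with PRR9 and GI ranking at least 97.4 in each list, 18 of 20 light-signalling genes (interval 68.3 to 98.8%), including the blue-light receptor gene CRY1, and 21 of 24 auxin genes (87.5%, 67.6 to 97.3), including IAA2, an early auxin-response gene. Cold, heat and drought genes (13 of 15, with CBF3 and COR47), housekeeping genes (12 of 14) and genes known for natural variation (16 of 20, with the disease-resistance regulator ACD6 and the seed dormancy gene DOG1) also lay above the middle 95% of 10000 random lists matched on the space around genes. Some natural variation genes, such as FLC, PHYC and ELF3, also stand on the flowering, light or clock lists, so these lists are not independent. With a narrower window, 500 bp outside to 100 bp inside, the natural variation genes fell to 11 of 20, inside the range of random lists (percentile 80.0), and the other 6 lists stayed above it. With the gene and 2000 bp on each side, cold, heat and drought, housekeeping and natural variation genes were inside the range. By region the order of lists differed. Of the regions in these windows, 71.2% were in all 4 accessions for photosynthesis, 66.7% for the clock, 64.6% for auxin and 62.3% for light. Cold, heat and drought genes had 71.1%, housekeeping genes 58.8% and natural variation genes 55.8%. Flowering-time genes had 76.1%, the highest of the 17 lists, and all regions together 54.3%. A place among random lists describes these libraries and is no test.

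Lists of flowering, glucosinolate, immune receptor, seed, floral, cell cycle and tissue marker genes were not above that range. Flowering-time genes were open in all 4 accessions in 14 of 20 cases, including the floral repressor genes FLC and SVP, and FT, the florigen gene, had no peak at its ends in any list. Glucosinolate genes reached 13 of 21, with no peak at the myrosinase genes TGG1 and TGG2. NLR immune receptor genes, whose products detect pathogens inside the cell, reached 11 of 24 (45.8%, 25.6 to 67.2), a value at percentile 31.0, and 8 of the 24 had no peak at their ends in any accession, among them RPS4, RRS1, RPP4 and RPP5. Root markers reached 7 of 12, shoot, epidermis and stomata markers 9 of 15, floral organ identity genes 6 of 12, cell cycle genes 3 of 5 and vascular markers 2 of 6. Seed and embryo genes were the lowest of the 17 lists, with 5 of 16 (31.2%, 11.0 to 58.7) at percentile 3.21, and 7 of the 16 had no peak at their ends in any list, among them the storage protein genes SESA2, SESA3 and SESA4. They fell to 2 of 16, below the range at percentile 0.375, with the narrower window, and rose to 8 of 16, inside it and above the vascular markers, with the gene and 2000 bp on each side. Without Bur-0, 7 of 16 seed and embryo genes (43.8%) were open in all the other accessions, again above the vascular markers (33.3%).

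Among the 260 list genes, 22 had a peak in exactly 3 accessions or exactly 1. Of the 19 called in 3, Bur-0 was the accession without a call for 13. These were ZTL, a blue-light F-box protein of the clock, FCA, of the autonomous flowering pathway, COR15A, a cold-induced chloroplast protein, the NLR genes LAZ5 and RPP2A, PP2AA3, a phosphatase subunit used as a reference gene, OLE1, an oleosin, LEC1, LFY and WUS, master regulators of embryo, flower and stem cells, WER and FAMA, which specify epidermal and guard cell fates, and CYCB1;1, a mitotic cyclin. Among all 2315 protein-coding genes called in 3 accessions, Bur-0 lacked the call in 1361 (58.8%) and Tsu-1 in 611 (26.4%). Tsu-1 had no call at PHYC, a phytochrome, TSF, a relative of FT, ABI3, a seed regulator, and EXPA7, a root hair expansin. Bay-0 had none at PDF2, an epidermal homeobox gene, nor at RPP7, a downy mildew resistance gene whose region ranked 95.1 in Bur-0, 80.8 in Est-1 and 50.6 in Tsu-1. Genes called in 1 accession were PHOT1, a phototropin, and CLV3, a stem-cell peptide, in Est-1, and VIN3, a vernalization gene, in Bay-0, with ranks of 10.8, 25.6 and 13.3. Apart from RPP7 and LAZ5, whose best rank was 58.3 in Est-1, and COR15A, at 52.2 in Est-1, the 22 genes ranked below 50 in every list that called them.

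Homeobox transcription factor genes were open in all 4 accessions more often than matched genes under each gene window, and cytochrome P450 genes lay near the lower edge of the matched range or, with the widest window, below it. Families were collected by keyword in gene symbols and synonyms, so unnamed members were not counted. Homeobox genes had a peak in all 4 accessions for 55 of 67 members (82.1%, 70.8 to 90.4), against a median of 52.2% of the members in matched random lists. WRKY genes reached 50 of 72 (69.4%, 57.5 to 79.8), MYB genes 90 of 147, histone-named genes 46 of 65, chlorophyll-named genes 29 of 37 and SAUR genes, auxin-induced growth regulators, 54 of 80, all above the middle 95% of random lists. MYB genes depended on the window: with the narrower one they fell to 57 of 147 (38.8%), below the 45.3% of all protein-coding genes and inside the range of random lists, while homeobox (73.1%), WRKY (62.5%), histone-named, chlorophyll-named and SAUR genes stayed above it. With the widest window WRKY and histone-named genes were inside the range. Inside it in the first window lay heat shock genes (35 of 52), bHLH genes (21 of 31), F-box genes (20 of 31), receptor-like genes (47 of 79), glutathione S-transferase genes (26 of 45), ribosomal genes (40 of 70), disease resistance genes (6 of 13), pentatricopeptide genes (5 of 12) and cytochrome P450 genes. The last had 112 of 232 members open in all 4 accessions (48.3%, 41.7 to 54.9) at percentile 4.74, and 130 (56.0%) at percentile 0.995 with the widest window. Heat shock (33 of 52) and bHLH genes (21 of 31) lay above the range with the narrower window, and heat shock genes also with equally long lists. Ribosomal genes were open in some but not all accessions for 21 of 70 members (interval 19.6 to 42.1%) at percentile 96.9, against a random median of 20.0%.

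Regions missing from an accession stood next to each other more often than random reassignment gave. Bur-0 had 526 neighbouring pairs of missing regions, against 391 on average and at most 435 in 100 random reassignments. Counts were 99 in Tsu-1 (random mean 66.4), 46 in Est-1 (27.9) and 41 in Bay-0 (24.1), each above its highest random count of 89, 44 and 35. The longest run held 9 regions without a Bur-0 peak on chromosome 5, from 15144441 to 15168730 (24.3 kb), where the longest random run was 7; the stretch holds AT5G38010 and AT5G38020. Ranks of the other lists within it ran from 0.0621 to 95.6. Among regions ranked above 50 in each of the other lists the counts were 17 in Bur-0, 6 in Est-1, 3 in Bay-0 and 1 in Tsu-1, and none exceeded its highest random count.

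**Figure D3:**
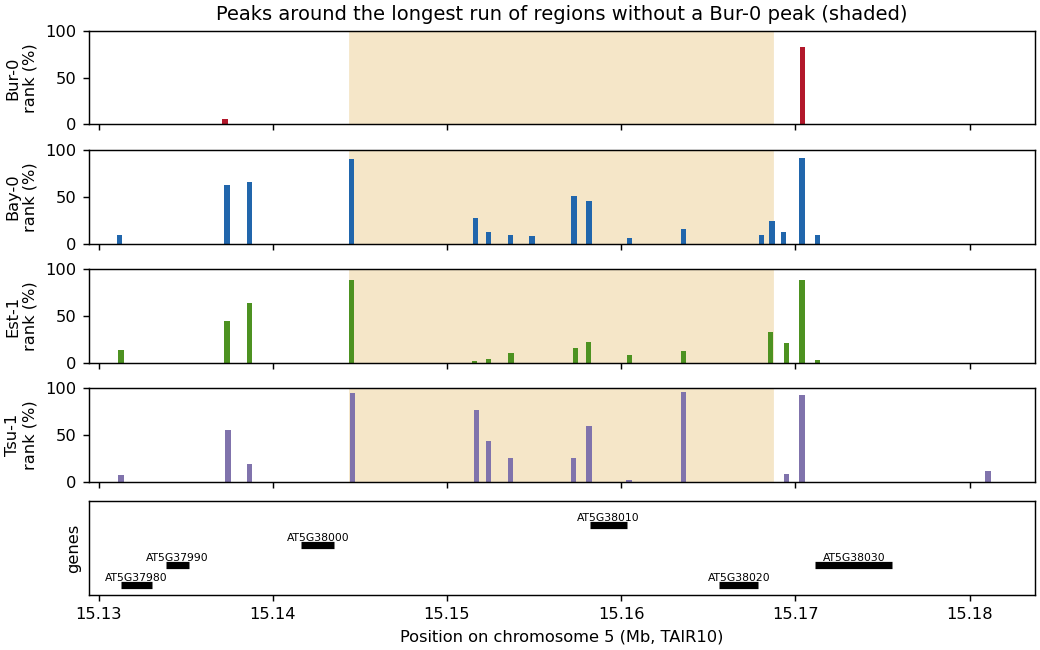
Peaks of the 4 accessions around the longest run of regions without a Bur-0 peak (horizontal axis, position on chromosome 5 in Mb, TAIR10; vertical axes, rank percentile of each peak within its list); bars are peaks, shading marks the run and black bars are genes. Within the shaded 24.3 kb the Bur-0 track has no peak, while Bay-0, Est-1 and Tsu-1 each have peaks throughout.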

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

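No explanation was tested in this part, and no test in it was chosen after the results had been seen. Peaks were also called on the organelle chromosomes, which no comparison of the accessions uses, and each count lay above the limit of 3 that a count of 0 allows. Chloroplast peaks numbered 225 in Bur-0, 252 in Bay-0, 248 in Est-1 and 242 in Tsu-1, with a median signal of 16731, 16578, 15134 and 10284. Mitochondrial peaks numbered 44 in Bur-0, 44 in Bay-0, 53 in Est-1 and 4 in Tsu-1.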

How the results depend on the processing

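Alternatives chosen only after the data were seen were the wider gene window, placement at gene ends, lists without one accession, random lists matched again under each gene window and missing regions without an own peak within 300 bp. No paired analysis was possible because each accession has 1 library and the labels give no replicate numbers. Of the alternative values for the main results, 35 stayed within their interval or within 1.5 times the count and 65 moved further. Bur-0 had the highest count of missing regions, and its pairs the lowest sharing, under each alternative run. Among list and family values, 12 of 226 moved. The count of short motifs in 300 bp windows was not run, since no genome sequence was used. Depth is unknown here, so which absent calls came from low depth was not tested. Keeping fewer peaks lowers the peak counts, and a stricter overlap the pairwise sharing, by construction; for the other changes the cause was not tested.

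Keeping the stronger 50% of each list left 12649 peaks in Bur-0, 14410 in Bay-0, 14849 in Est-1 and 13694 in Tsu-1. Sharing was then 78.4% for Bur-0 and Bay-0, 76.3% for Bur-0 and Est-1, 78.6% for Bur-0 and Tsu-1, 84.7% for Bay-0 and Est-1, 83.7% for Bay-0 and Tsu-1 and 82.6% for Est-1 and Tsu-1. Regions numbered 18788, with 9323 (49.6%) in 4 accessions, 3034 in 3, 2647 in 2 and 3784 in 1. With an overlap of at least 50% of both peaks the same pairs shared 70.7, 68.9, 70.3, 79.0, 76.7 and 76.4%, 10895 regions were called in 1 accession and 40.4% in all 4.

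Equally long lists put 56.0% of regions in all 4 accessions and gave 82.3% sharing for Bur-0 and Bay-0, 81.2% for Bur-0 and Est-1, 81.8% for Bur-0 and Tsu-1, 85.8% for Bay-0 and Tsu-1 and 85.4% for Est-1 and Tsu-1. Bur-0 then lacked 1850 regions and had 2235 private ones, while Est-1 had 1254 private ones, so the accession with the most private regions changed from Est-1 to Bur-0. The Bur-0 list, the shortest, was not cut, so by construction its private count could only rise. This change therefore does not describe Bur-0 itself. Genes open in all 4 accessions were 49.9%, and in some 18.1%. Merging peaks up to 150 bp apart left Bur-0 with 905 private regions and put 60.4% in all 4 accessions.

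Counting only regions ranked above 50 in every list that calls them, Bur-0 lacked 378 and had 291 private, Bay-0 123 and 137, Est-1 135 and 225, and Tsu-1 127 and 128. Counting only missing regions with no own peak within 300 bp gave 2295 in Bur-0, 415 in Bay-0, 457 in Est-1 and 810 in Tsu-1. Of the 378, 123, 135 and 127 strong ones, this left 110, 37, 42 and 34. Runs among strong regions gave 3.47 times the random pairs in Est-1 and 0.581 times in Tsu-1, from 6 pairs and 1 pair.

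Leaving out one list put 64.6% of regions in all 3 others without Bur-0, 58.3% without Bay-0, 59.6% without Est-1 and 58.9% without Tsu-1. Without Bur-0, all 16 clock genes and 14 of 15 cold, heat and drought genes were open in the other 3 accessions.

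With a 200 bp window, gene ends held 43.6% of peaks in Bur-0, 45.4% in Bay-0, 44.7% in Est-1 and 43.7% in Tsu-1, with 45.7% of regions in 4 accessions and 35.9% of those in 1, against 16.0% of random positions. With all annotated genes the values were 60.1, 61.7, 61.3, 60.1, 61.5 and 55.4%, against 37.8%. A gene window of 500 bp outside to 100 bp inside gave 45.3% of genes open in all 4 accessions and 21.0% in some, with natural variation genes down to 11 of 20, MYB genes to 38.8% and cytochrome P450 genes to 90 of 232; the gene with 2000 bp on each side gave 63.3 and 17.8%, with MYB genes up to 74.8%, SAUR genes to 64 of 80 and cytochrome P450 genes to 56.0%.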

Other observations

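The tests of runs, of the rank of missing regions, of the missing rate among strong regions and of own peaks lying on a peak of another list, and the counts by class of gene and of the strongest peaks, were chosen after the results had been seen. Open chromatin at genes that make no protein differed by class. A peak within the gene or 200 bp of it was called in all 4 accessions for 39.9% (39.3 to 40.5) of protein-coding genes, 30.5% (20.8 to 41.6) of 82 snRNA genes, 26.8% (25.3 to 28.3) of lncRNA genes and 26.1% (22.7 to 29.7) of 625 tRNA genes. It was lower for snoRNA genes, 11.5% (8.05 to 15.8), and miRNA genes, 8.59% (5.78 to 12.2), and stood at 0.945% (0.666 to 1.3) for 3917 pseudogenes. Transcribed pseudogenes, counted apart, stood at 6.70% (5.17 to 8.50). Of 140 pseudogenes with a peak in any list, 73.6% (65.5 to 80.7) lacked one in another, the highest share of any class. It was 59.5% (51.3 to 67.3) for transcribed pseudogenes and 35.0% (34.3 to 35.8) for protein-coding genes. The pseudogene interval overlaps those of transcribed pseudogenes, miRNA genes (39.1 to 65.7) and antisense RNA genes (28.9 to 75.6). Genes differ in length between classes, from a median of 73 bp for tRNA to 2078 bp for protein-coding genes. Longer genes have more room for a peak. Pseudogenes, with a median of 2043 bp, are about as long as protein-coding genes, so length does not account for their low share. Other causes, such as how well reads map to pseudogenes, were not tested.

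The strongest peaks of Bur-0 lay in gene-poor sequence and at ribosomal RNA genes. Of its 10 strongest peaks, 7 were in gene-poor 100 kb bins, against 3 in Bay-0, 4 in Est-1 and 2 in Tsu-1, and 3 were within 10 kb of a ribosomal RNA gene, against 0 in each other list. The highest Bur-0 signal, 7542 on chromosome 3 from 13591961 to 13592110, was 58.0 times its list's median, while the highest of the other lists were 16.9 times in Bay-0, 14.0 times in Est-1 and 13.8 times in Tsu-1. Around the 45S ribosomal RNA genes on chromosome 2, Bur-0 had 9 peaks with a median rank of 99.9, and Bay-0, Est-1 and Tsu-1 had 6, 6 and 5 with medians of 69.8, 68.8 and 81.3. Around those on chromosome 3 the lists differed less by these measures, with 11, 11, 11 and 12 peaks in Bur-0, Bay-0, Est-1 and Tsu-1 and median ranks of 99.9, 98.4, 98.7 and 93.3. The highest signal there was 2453 in Bur-0, whose list median was 130. In Bay-0, Est-1 and Tsu-1 it was 714, 973 and 656, with list medians of 155, 172 and 108.

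Bur-0 lacked the most regions that the other 3 lists held. Its shorter list was not the whole reason, as its count stayed 1.85 times the next highest with equally long lists (2.55 times with full lists), nor were deletions or unmappable stretches over several regions, since runs held only 7.01 percentage points more of the missing regions than chance gave. More background among the Bur-0 calls stays open, since their location does not settle it. Gene ends held 55.5% (54.8 to 56.1) of Bur-0 peaks and 55.4% of Tsu-1 peaks. The share was higher in Bay-0, at 57.0% (56.5 to 57.6), and in Est-1, at 56.6%. Private regions of Bur-0 were there in 42.8%, against 45.4% in Tsu-1, 54.2% in Bay-0 and 52.3% in Est-1. The median −log10 p of peaks was also lowest in Bur-0, at 39, against 45 in Tsu-1, 56 in Bay-0 and 69 in Est-1. Whether background lowered it was not tested. Weak regions near the calling threshold could be part of it, as the missing regions had a median rank of 25.6 in the other lists. Those missing from Tsu-1 had a similar median (25.0). Strong regions formed unlike sets, with 11004 for Bur-0 and 9721, 9784 and 9945 for Bay-0, Est-1 and Tsu-1. For those 3 accessions a region also had to rank above 50 in Bur-0, so the rates are not like for like. Among regions ranked above 50 in the other lists the Bur-0 missing rate was 2.49 times the next highest. Weakness in those lists may thus not be the whole reason. Of the 378 such regions that Bur-0 lacked, 268 had a Bur-0 peak within 300 bp. An own peak was as near for 86 of 123 in Bay-0, 93 of 135 in Est-1 and 93 of 127 in Tsu-1. A biological difference of Bur-0, or its sequence distance from the Col-0 reference at single sites, stays open and was not tested. The same holds for the sequencing depth, digestion and quality of the Bur-0 library. Without replicate libraries these cannot be told apart from accession, and equally long lists do not remove them.

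Of the 48 regions private to Bur-0 that ranked above 90, 33.3% (20.4 to 48.4) were in gene-poor bins. The counts elsewhere were 0 of 10 in Bay-0 (interval 0 to 30.8%), 2 of 19 in Est-1 (1.3 to 33.1%) and 0 of 17 in Tsu-1 (0 to 19.5%), and the first 2 intervals overlap that of Bur-0, so a difference from these lists is not shown. Reads of repeated sequence piling up in that library could give this, and would also raise gene-poor regions shared by all. The 473 such regions ranked -0.317 points apart in the median (bootstrap interval -2.06 to 0.941), which leaves the explanation open since the interval spans 0. No biological explanation was tested.

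Of the 5610 regions missing from an accession, 836 lay within 150 bp of one of its own peaks, which could come from displaced calls of a single site. In 61.7% (58.3 to 65.0) of them the own peak lay on a peak of another list, which so called both places. The share was 65.6% (60.4 to 70.4) of the 363 that ranked above 50 in each of the other lists. This does not settle how many were displaced, because overlap with 1 other list was enough. The own peak lay on no other list in 320 of the 836, while private regions were only 4.36 to 7.38% of the regions a list called. Among the 125 of the 363 whose own peak lay on no other list, 83.2% (75.5 to 89.3) had an own peak ranked above 50. Displaced calls of a strong site would give this, so displacement remains an explanation for them. Distances alone decide nothing, because peaks of a list keep apart: strong regions with a call had another own peak within 150 bp in 6.73% and at 300 to 450 bp in 38.2%, and those without a call had one in 47.6% and 41.0%. No biological explanation was tested.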
